A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

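Poly(A) RNA was sequenced in 1 library of ZTW1, a wild type bioethanol strain of Saccharomyces cerevisiae, and 1 of its mutant ZGR3. Per the labels' protocols, cells grew in YPD (10 g/L yeast extract, 20 g/L peptone, 20 g/L glucose), RNA was extracted with hot phenol, treated with DNase for 30 min, and poly(A) RNA was made into Illumina libraries. The labels do not say what the mutation in ZGR3 is or how it arose.

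The deposited tables give, per the file headers, a count of uniquely assigned reads per gene, and the counts summed to the total in the header, 4.66 M for ZTW1 and 4.61 M for ZGR3. The authors also gave RPKM, reads per kilobase of listed length and per M reads of that total, which the reads, length and total gave back for all 5659 genes. The authors' coverage column, per the file headers a percent of the gene's length covered by reads, was used only to judge shared reads and in the closing observations. Genes with 1 read covered a median of 49 bases. Genes without reads in a library were absent from its table and were set to 0. All 5659 listed lengths were multiples of 3, so they are called coding length. The genome build was sacCer2, per the submitters' processing notes. The aligner, the read filters and the handling of strand are not given in the sources used here, so reads of a gene and an overlapping or antisense neighbour cannot be told apart. TAR1, which lies antisense to ribosomal RNA, held 0.882% of reads in ZTW1 and 0.860% in ZGR3.

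Gene IDs were matched to the RefSeq table of assembly R64 for names, chromosomes and gene order only; 5653 matched and 6 did not. No coordinates are given because the builds differ. Symbols are those of the deposited tables.

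The main value was log2((RPKM ZGR3 + 1)/(RPKM ZTW1 + 1)) for 5532 genes with a mean RPKM of at least 1, which understates differences of low genes. With 1 library per strain no test was possible, so genes were counted by a rule of size, 2-fold. Folds of reads per total reads carry exact 95% counting intervals from the Clopper-Pearson interval of the binomial share, and a gene without reads was set to a floor of 3 counts. Reads carry no molecular identifiers, so intervals and floors cover counting error only.

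Lists of genes, 40 in all, were fixed before the data were examined, as were the design, the rule for named genes and the alternatives not named below as added. The median log2 ratio of each list with at least 5 genes was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. The list of mitochondrially encoded genes had 1 gene measured and was not computed; such genes held 32 reads in ZTW1 and 24 in ZGR3. Lists taken by name patterns hold a few genes with other functions, among them YMR1, RPP1 and MRP8, and 13 genes of the general stress list are also in other lists. Medians carry 95% intervals from 1000 Poisson redraws of the reads. Chromosome medians were ranked in the same way, and windows of 25 consecutive genes were set against 1000 shuffled gene orders. Divisions of a chromosome, with at least 10 genes on each side, were set against 100 shuffled orders.

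Named genes were the 12 highest and 12 lowest log2 ratios among nuclear genes with a mean RPKM of at least 10, and the 2 members of each list furthest from 0, or up to 4 for a list standing apart. The 2 genes with the highest mean RPKM of each chromosome or window standing apart were added, and GPD1, GPD2, ADH1, ADH2, PDC1, HSP104, TPS1 and ACT1 were always named. The same was done for the chromosome segments, which were found later. A result on 1 further gene group is not reported here. Genes with near-identical copies, such as SSB1, TEF1, TEF2, HXT6, THI11, SNZ2, SNZ3, ERR3, RPL41A, RPS16B, SAM1, SAM2 and the FLO and PAU families, can share reads and are uncertain.

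The steps were tested on simulated data for 5526 genes. The 2-fold rule recovered 91 of 100 genes changed by 2.5-fold and 100 of 100 changed by 4-fold, and 44 of 5238 unchanged genes passed it through counting noise. A simulated list raised by 0.4 reached percentile 100 and an unchanged list percentile 5. A simulated region of 60 genes was found with 13 extra genes, and 960 of 1000 counting intervals held the true fold. The simulated region was lowered by 0.5 (log2), more than the segments of chromosomes VIII, XI and XIV described below were shifted. Simulated unchanged genes varied by counting noise only, so these recovery rates may not hold for the real libraries.

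Alternatives were pseudocounts of 0.1 and 5 RPKM, centring on the median, trimmed mean of M values scaling, other filters on low values, reads per M reads, subtraction of chromosome medians, a 3-fold rule and unmatched random lists. Added after seeing the data were a correction for coding length by a running median of 401 genes, random lists matched on length and expression, and leaving out the segments' genes or the 15 outermost genes at each chromosome end. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with edgeR 4.0.16 in R 4.3.3 for the scaling factors alone.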

Results

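Transcript levels were measured by RNA sequencing in 2 strains of the budding yeast Saccharomyces cerevisiae, with 1 library per strain. ZTW1 is a wild type strain used for bioethanol production, and ZGR3 is a mutant derived from it. Both were grown in 25 mL of YPD, a rich medium with 20 g/L glucose, from an optical density at 600 nm of 0.05, and RNA was taken as the cultures entered early stationary phase. The ZTW1 library held 4.66 M reads (M, mega) assigned to genes and the ZGR3 library 4.61 M. At least 1 read was counted for 5626 genes in ZTW1 and 5612 in ZGR3, and the median gene had 190 and 185 reads. SED1, a cell wall protein gene, took the most reads in both, 4.32% of the ZTW1 total (95% Clopper-Pearson interval 4.30 to 4.34) and 4.56% of the ZGR3 total (4.54 to 4.58). With 1 library per strain no difference below has a replicate check and none carries a p-value. The intervals cover counting error only, so they compare these libraries and not the strains.

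The comparison of ZGR3 with ZTW1 asks how the transcript profile of the mutant differs from that of its parent. HXT4, a hexose transporter gene, had the log2 ratio furthest from 0 of the named genes, −4.42, and was 27.8-fold lower in ZGR3 (95% counting interval 18.7 to 43.2). Genes for iron uptake, invertase and inositol synthesis were also among the lowest, while SPS100, HSP26 and CTT1 were among the highest. Of 5532 genes with a mean RPKM of at least 1, 30 were at least 2-fold higher in ZGR3 and 106 at least 2-fold lower, on the log2(RPKM + 1) scale. The other 5396 genes, or 97.54%, lay within 2-fold. The counting interval excluded equality for 20 of the higher and 81 of the lower genes. Across genes, which are not independent replicates, log2(RPKM + 1) in both libraries correlated with Pearson's r of 0.980 and Spearman's rho of 0.978.

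Among the 12 genes highest in ZGR3, SPS100, a spore wall gene, went from 2141 reads in ZTW1 to 9135 in ZGR3, 4.31-fold higher (4.12 to 4.52). NCA3, of the SUN family of cell wall proteins, was 2.69-fold higher (2.56 to 2.82). HSP26, encoding a small heat shock protein, was 2.52-fold higher (2.45 to 2.59), and CTT1, the cytosolic catalase, 2.12-fold higher (2.08 to 2.16). CIT2, the peroxisomal citrate synthase, was 2.32-fold higher (2.24 to 2.41). The zinc finger gene STP4 was 2.35-fold higher (2.20 to 2.52), ICY1 2.24-fold (1.97 to 2.55) and the NADPH oxidoreductase gene OYE2 2.20-fold (1.99 to 2.44). PDC6, a minor pyruvate decarboxylase, was 2.07-fold higher (1.81 to 2.38). The uncharacterised gene YDL218W had 37 reads in ZTW1 and 107 in ZGR3, a log2 ratio of 1.44. DOG2 had 17 and 52 reads and ERR3 57 and 160 reads, with log2 ratios of 1.45 and 1.41. Both have close paralogs that can share reads, so their values are uncertain.

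**Figure D1:**
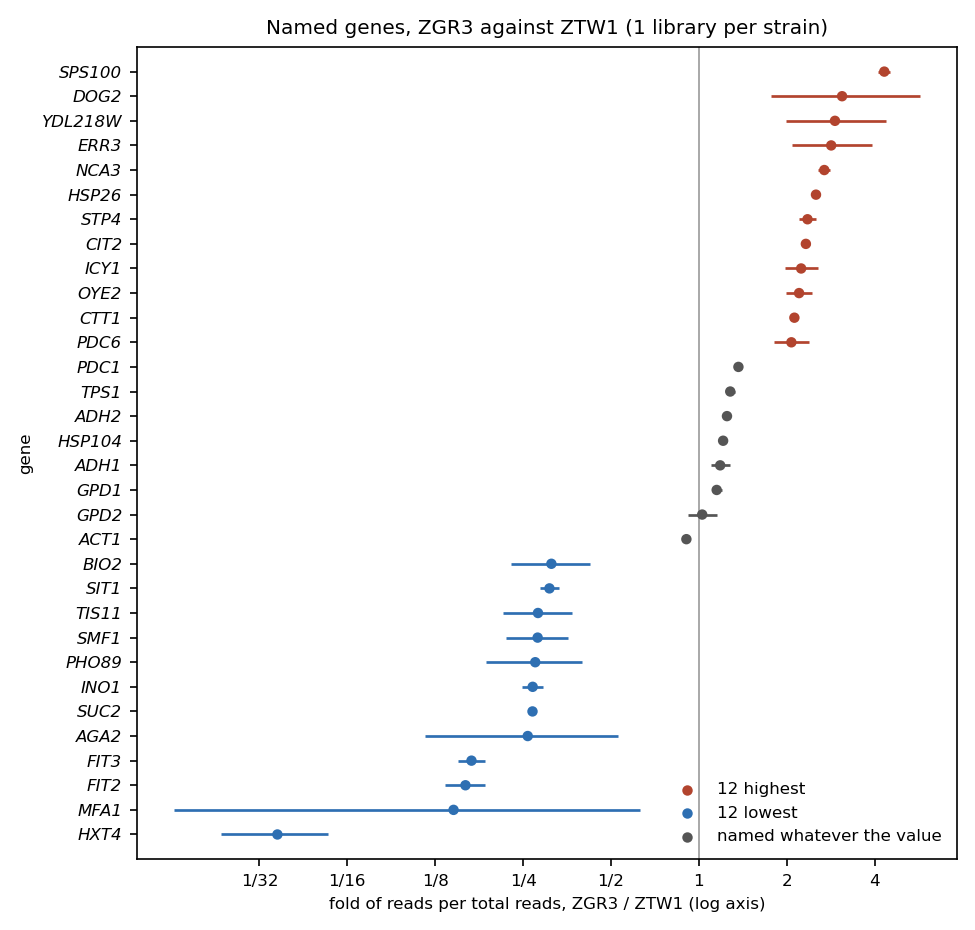
Fold of reads per total reads in ZGR3 over ZTW1, on a log axis, for the 12 highest and 12 lowest genes and the 8 genes named whatever their value; points are folds, lines are 95% counting intervals, and each strain has 1 library. HXT4 lies furthest left, with 702 reads in ZTW1 and 25 in ZGR3, and SPS100 furthest right at 4.31-fold.

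Among the 12 genes lowest in ZGR3, HXT4 had 702 reads in ZTW1 and 25 in ZGR3. These covered 69.5% of its length in ZTW1 and 45.1% in ZGR3, and sharing of reads with other hexose transporter genes was not tested. FIT2 and FIT3, which encode cell wall mannoproteins that retain siderophore iron, were 6.30-fold lower (5.39 to 7.4) and 6.01-fold lower (5.40 to 6.71). The siderophore transporter gene SIT1 was 3.25-fold lower (3.02 to 3.50). TIS11, whose product binds messenger RNAs during iron shortage, was 3.56-fold lower (2.73 to 4.69), and BIO2, the biotin synthase, 3.20-fold lower (2.35 to 4.41). SUC2, encoding invertase, went from 25928 to 6903 reads, 3.71-fold lower (3.62 to 3.82). INO1, the enzyme that starts inositol synthesis, was 3.71-fold lower as well (3.42 to 4.03). The manganese transporter gene SMF1 was 3.57-fold lower (2.81 to 4.56) and the phosphate transporter gene PHO89 3.64-fold lower (2.51 to 5.38). MFA1, a mating pheromone gene, had 14 reads in ZTW1 and 2 in ZGR3, a ratio of 6.92 with a counting interval of 1.59 to 62.8. AGA2, for a subunit of the mating agglutinin, had 39 and 10 reads.

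Genes of ethanol and glycerol metabolism named whatever their values lay within 2-fold. ADH2, the alcohol dehydrogenase that oxidises ethanol, was 1.25-fold higher in ZGR3 (1.24 to 1.26), and ADH1, the fermentative isozyme, 1.18-fold higher (1.10 to 1.27). ADH1 had 1321 reads in ZTW1 and 1545 in ZGR3, against 85674 and 105732 for ADH2. Sharing of reads between these paralogs was not tested. PDC1, the main pyruvate decarboxylase, was 1.37-fold higher (1.34 to 1.39). The glycerol phosphate dehydrogenase gene GPD1 was 1.15-fold higher (1.11 to 1.196), and for GPD2 a difference was not detectable at this depth (1.03-fold, 0.915 to 1.15). The disaggregase gene HSP104 was 1.21-fold higher (1.18 to 1.25) and the trehalose phosphate synthase gene TPS1 1.28-fold higher (1.23 to 1.33). Actin, ACT1, was 1.10-fold lower (1.07 to 1.13).

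Groups of genes fixed before the data were examined were set against 10000 random lists of the same size and mean expression, as a description of these libraries. Genes of iron uptake, sterol and fatty acid synthesis and mitochondrial translation and respiration were lower in ZGR3 as groups. Genes for chaperones, the proteasome, DNA repair, ribosome biogenesis, and aminoacyl-tRNA synthetases and translation factors were higher. Of 39 lists computed, 7 stood apart as higher and 9 as lower, where 1.95 would be at those percentiles if all were random. A list stood apart when its median log2 ratio lay in the lowest or highest 2.5 percent of the random medians.

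The iron regulon had a median log2 ratio of −0.48 (percentile 0), with 26 of 32 genes below 0 and 10 at least 2-fold lower. FIT2 (−2.64), FIT3 (−2.58), the reductase gene FRE7 (−1.97) and TIS11 (−1.78) were its furthest members. Ergosterol biosynthesis had a median of −0.50 (percentile 0), and 24 of 25 genes lay below 0. Its furthest members were CYB5 (−1.11), the 1 member at least 2-fold lower, ERG28 (−0.96), ERG2 (−0.88) and HMG1 (−0.82), a reductase of the sterol pathway. Fatty acid synthesis and desaturation had a median of −0.42 (percentile 0), with 11 of 14 genes below 0 and none 2-fold apart. OLE1, the desaturase, was at −0.76, the carboxylase gene ACC1 at −0.70, the synthase gene FAS1 at −0.66 and PHS1 at −0.59.

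Mitochondrial ribosomal protein genes had a median of −0.40 (percentile 0), with 64 of 70 below 0. MRPL32 (−1.02) was the only member at least 2-fold lower, followed by MRPS18 (−0.99), MRPS8 (−0.89) and MRPL44 (−0.81), and 8 members lie on the chromosome segments described with the chromosome medians. Nuclear genes for the respiratory chain and ATP synthase had a median of −0.31 (percentile 0), with 33 of 35 below 0 and none 2-fold apart. ATP20 was at −0.79, CYC1, a cytochrome c gene, at −0.56, RIP1 at −0.51 and COX7 at −0.51. Shorter genes were lower in ZGR3 in general, with medians of −0.15 in the shortest and 0.10 in the longest of 10 classes of coding length. After correction for this trend, chosen after seeing the data, the medians were −0.34 for the mitochondrial ribosomal list and −0.20 for the respiratory list.

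Vacuolar protease and ATPase genes had a median of −0.28 (percentile 0.08), with 15 of 22 below 0 and none 2-fold apart. VMA5 was at −0.54, LAP4 at −0.53, PPA1 at −0.53 and VMA9 at −0.36. VMA5 and LAP4 lie on the segment of chromosome XI described with the chromosome medians. Thiamine and pyridoxine genes had a median of −0.35 (percentile 0.07), with 19 of 23 below 0 and 2 at least 2-fold lower. THI11 had 14 reads in ZTW1 and 0 in ZGR3, at least 4.62-fold lower against a floor of 3 counts in ZGR3 if the 14 reads are taken as exact. The counting interval, which also covers the error of the 14 reads, allows 3.28-fold. The list's median stayed at −0.35 with THI11 at the floor. The phosphatase gene PHO3 was at −1.09, SNZ2 at −0.84 and SNZ3 at −0.78. Sulfur amino acid biosynthesis had a median of −0.32 (percentile 0.05) with a Poisson interval of −0.37 to 0.03, which includes 0, and had 14 of 23 genes below 0 and 3 at least 2-fold lower. These were SAM1 (−1.66) and SAM2 (−1.50), which make S-adenosylmethionine, and MET17 (−1.29), while the methionine synthase gene MET6 was at −0.89. It did not stand apart under 3 of 13 alternative settings, with a median of −0.06 at a mean RPKM of at least 10, −0.14 with a pseudocount of 5 RPKM and −0.15 after subtraction of chromosome medians (percentiles 29.25, 3.44 and 5.13). Genes specific to a or alpha cells had a median of −0.44 (percentile 1.22), with 9 of 10 below 0, and of −0.24 with a pseudocount of 5 RPKM. It did not stand apart under 6 of the settings. Its percentile was 3.32 without the filter on low values, 3.65 after subtraction of chromosome medians, 3.73 against lists matched on length and expression, 6.9 without the genes of the chromosome segments and 3.98 without the outermost genes of each chromosome, and at a mean RPKM of at least 10 it had 3 genes, too few to compute. MFA1 (−2.52) and AGA2 (−1.83) were at least 2-fold lower, and MF(ALPHA)2 (−0.68) and STE3 (−0.67) had at most 14 reads in either library.

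Heat shock proteins and chaperones had a median of 0.28 (percentile 100), with 23 of 29 genes above 0. HSP26 was the 1 member at least 2-fold higher (1.33), SSA4 was at 0.84 and BTN2 at 0.71. SSB1, a ribosome-associated chaperone gene, was the 1 member at least 2-fold lower (−1.07). Proteasome genes had a median of 0.21 (percentile 100), with 31 of 34 above 0 and none 2-fold apart. RPN10 was at 0.73, RPN1 at 0.54, RPT3 at 0.45 and RPT4 at 0.44. DNA repair and ribonucleotide reductase genes had a median of 0.22 (percentile 100), with 24 of 34 above 0, and of 0.14 at a mean RPKM of at least 10. The mismatch repair genes MSH6 and MSH3 were at 0.82 and 0.64 and the glycosylase gene OGG1 at 0.70. HUG1 was at −1.32 with 9 and 3 reads.

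Ribosome biogenesis genes had a median of 0.14 (percentile 99.96), with 39 of 56 above 0 and none 2-fold apart, and a median of 0.09 after correction for coding length. NOP14 (0.68) and NUG1 (0.51) were above 0, NOP15 (−0.68) and EBP2 (−0.54) below. Aminoacyl-tRNA synthetases and translation factors had a median of 0.14 (percentile 99.79), with 33 of 46 above 0. The lysyl and leucyl synthetase genes KRS1 and CDC60 were at 0.42 and 0.37. TEF2 (1.02) and TEF1 (−0.36) are near-identical copies whose reads covered only 7.04% to 12.3% of their length, so their values are uncertain. Glycolysis had a median of 0.16 (percentile 99.35; Poisson interval 0.13 to 0.19), with 11 of 16 genes above 0. It did not stand apart against random lists matched on length and expression (percentile 96.3), or after correction for coding length, where its median was 0.12 (percentile 93.0). The hexokinase gene HXK1 was at 1.01, the enolase gene ENO2 at 0.87, the pyruvate kinase gene CDC19 at 0.59 and TDH2 at 0.32. The general stress response had a median of 0.09 (percentile 98; Poisson interval 0.06 to 0.11), with 21 of 32 genes above 0. It did not stand apart under 6 of the settings, in which its median was 0.09 to 0.11. Its percentile was 93.2 against lists matched on length and expression, 94.6 against unmatched lists, 95.9 after correction for coding length, 96.6 without the outermost genes, 97.25 after subtraction of chromosome medians and 97.3 without the segments' genes. HSP26, CTT1 (1.09) and HXK1 were at least 2-fold higher, while the aldehyde dehydrogenase gene ALD3 was at −0.43.

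**Figure D2:**
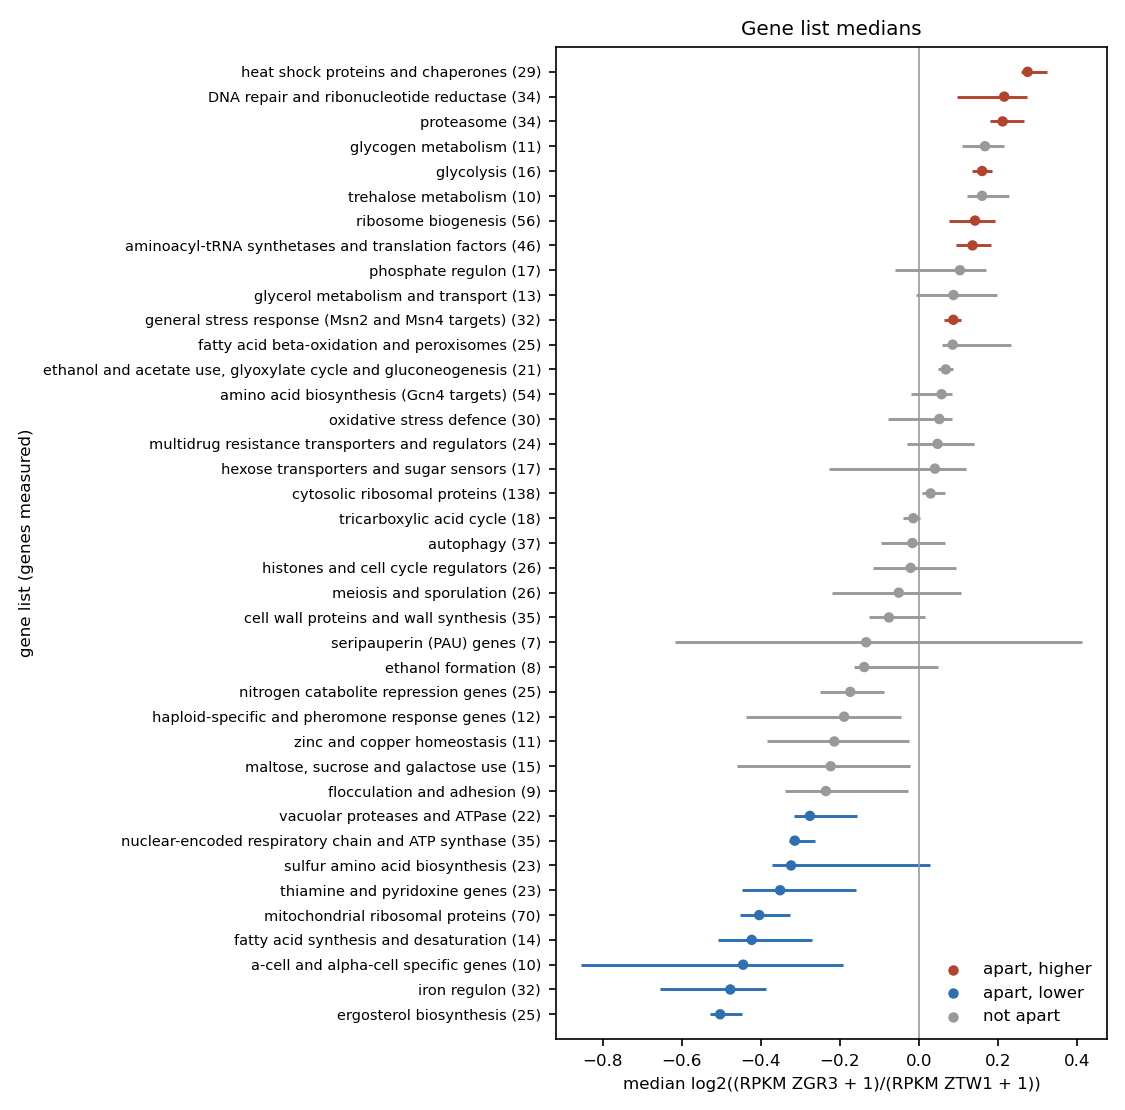
Median log2 ratio of RPKM + 1, ZGR3 over ZTW1, for the 39 gene lists, with the number of genes measured in parentheses; points are medians, lines are 95% intervals from 1000 Poisson redraws of the reads, and colours mark lists that stood apart. Ergosterol biosynthesis lies lowest at −0.50 and heat shock proteins and chaperones highest at 0.28.

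The other 23 lists did not stand apart. Among carbon metabolism lists, ethanol formation had a median of −0.14 (percentile 24.1), with PDC6 at 1.03 and PDC5 at −0.49. Ethanol and acetate use, with the glyoxylate cycle and gluconeogenesis, had a median of 0.07 (percentile 93.1), with CIT2 at 1.22 and the lactate transporter gene JEN1 at −0.88. The tricarboxylic acid cycle had a median of −0.01 (percentile 73.6), with SDH3 at −0.83 and CIT3 at 0.83. Trehalose metabolism was at 0.16 (percentile 96.0), with PGM1 at −0.61 and TPS1 at 0.36. Glycogen metabolism was at 0.17 (percentile 96.3), with PIG1 at 0.63 and GAC1 at 0.45. Glycerol metabolism was at 0.09 (percentile 84.98), with the dihydroxyacetone kinase genes DAK2 at 0.62 and DAK1 at 0.47. Peroxisomes and fatty acid oxidation were at 0.09 (percentile 92.4), with POX1 at 0.68 and IDP3 at 0.65. Hexose transporters had a median of 0.04 (percentile 81.7) with 2 of 17 genes at least 2-fold lower, HXT4 (−4.42) and HXT6. HXT6 had 46 reads in ZTW1 and 1 in ZGR3, a ratio of 45.5 (7.77 to 1836), but shares reads with the near-identical HXT7. Maltose, sucrose and galactose use was at −0.22 (percentile 5.22), with SUC2 at −1.89 and the isomaltase gene YOL157C at −1.34.

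Among nutrient and metal lists, Gcn4 targets of amino acid synthesis had a median of 0.06 (percentile 93.7), with ARG4 at −0.70 and ARG1 at 0.69. Nitrogen catabolite repression genes were at −0.17 (percentile 3.58), with DAL80 at −1.59 and DAL5 at −1.23. The phosphate regulon was at 0.10 (percentile 92.0), with PHO89 at −1.66 and PHM6 at −1.58 from 12 and 3 reads. Zinc and copper homeostasis was at −0.21 (percentile 5.46), with the copper transporter genes CTR1 at −1.06 and CTR3 at −1.02. Cell wall genes were at −0.08 (percentile 25.3), with the glucanase gene SCW11 at −1.28 and the mannoprotein gene CWP1 at −0.90. Flocculation genes were at −0.24 (percentile 10.7), with FLO5 at 0.57 and FLO9 at −0.48. Seripauperin genes were at −0.13 (percentile 33.1), with PAU12 at −1.07 from 4 and 1 reads and PAU7 at −0.83. Oxidative stress defence was at 0.05 (percentile 88.2), with OYE2 at 1.13 and CTT1 at 1.09. Multidrug resistance genes were at 0.05 (percentile 83.5), with RTA1 at −0.95 and the efflux pump gene PDR5 at −0.80.

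Among cell state lists, haploid-specific and pheromone response genes had a median of −0.19 (percentile 22.1), with RME1 at −0.89 and AXL1 at −0.78. Meiosis and sporulation was at −0.05 (percentile 52.8), with SPO19 at −1.43 from 8 and 1 reads and SPO11 at −1.42 from 12 and 1 reads. Histones and cell cycle regulators were at −0.02 (percentile 47.1), with the cyclin genes CLB3 at 0.63 and CLN2 at 0.61. Cytosolic ribosomal proteins were at 0.03 (percentile 86.3), with RPL41A at −1.19 from 12 and 5 reads and RPS16B at 0.69. RPS16B can share reads with its paralog RPS16A, so its value is uncertain. The genes of this list are short, and after correction for coding length their median was 0.14. They were at percentile 100 of random lists matched on length and expression. Autophagy was at −0.02 (percentile 45.6), with ATG10 at −0.97 and ATG12 at −0.83. Of the 16 lists standing apart, 12 kept this under each of 13 alternative settings. The general stress response and the a-cell and alpha-cell list each lost it under 6, sulfur amino acid biosynthesis under 3 and glycolysis under 2, and 7 other lists, cytosolic ribosomal proteins and nitrogen catabolite repression genes among them, gained it under at least 1.

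Genes of particular chromosome arms differed together. Chromosome XI had a median log2 ratio of −0.24 (percentile 0), with 224 of 308 genes below 0. Chromosome VIII was at 0.07 (percentile 100) and chromosome I at 0.09 (percentile 99.74), and the other 13 did not stand apart. The genes with the highest mean RPKM were FBA1 (0.16) and CWP2 (0.16) on chromosome XI, SOD2 (−0.08) and HXT5 (−0.43) on VIII, and CDC19 (0.59) and ACS1 (0.07) on I. In windows of 25 consecutive genes, medians outside the range of −0.53 to 0.37 reached in 1000 shuffled gene orders formed 2 regions. On chromosome VIII 91 genes from MSH1 to YHR213W had a median of 0.38, and on chromosome XI 29 genes from RPT1 to RAD27 a median of −0.52. The most abundant genes of these regions were SPS100 (2.11) and ENO2 (0.87) on VIII, and SDH3 (−0.83) and MRP8 (−0.67) on XI.

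Splitting each chromosome at its best dividing point, chosen after seeing the data, gave divisions beyond those of 100 shuffled orders on 4 chromosomes. On chromosome VIII the 86 genes from YHR127W to the right end had a median of 0.39 (95% Poisson interval 0.34 to 0.46), against −0.03 for the other 170. On chromosome XI the 175 genes from the left end to TTI1 had a median of −0.38 (−0.43 to −0.35), against 0.01 for the other 133; its most abundant genes, FBA1 and CWP2, went the other way, both at 0.16. Of these genes, 73 of the 86 on VIII lay above 0 and 161 of the 175 on XI below 0. On chromosome XIV the 47 genes from the left end to MRPL10 had a median of −0.36 (−0.45 to −0.29), with 41 below 0, KRE1 at −0.24 and YNL305C at −0.57, against −0.02 for the other 330. On chromosome XV the 10 leftmost genes, the smallest number allowed, had a median of −0.85 (−1.06 to −0.58), with the cell wall gene HPF1 at −0.92 and GRE2 at 0.34. Without the segments' genes the medians of chromosomes VIII and XI were −0.028 and 0.015. Several named genes lie on these segments, so their values may include the segments' shifts, which were not subtracted. They include VMA5, LAP4, FAS1, JEN1, SDH3, CWP1, PGM1 and EBP2 on XI, and SPS100, ENO2, OYE2 and RPN10 on VIII. MRPS18 and SNZ2 lie on that of XIV, and FRE7 and YOL157C on that of XV. Some lay well beyond their segment's median, such as SPS100 (2.11) and OYE2 (1.13) against 0.39, and FRE7 (−1.97) against −0.85. How much of each value goes with its segment was not tested. Without the segments' genes, 14 of the 16 lists still stood apart.

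**Figure D3:**
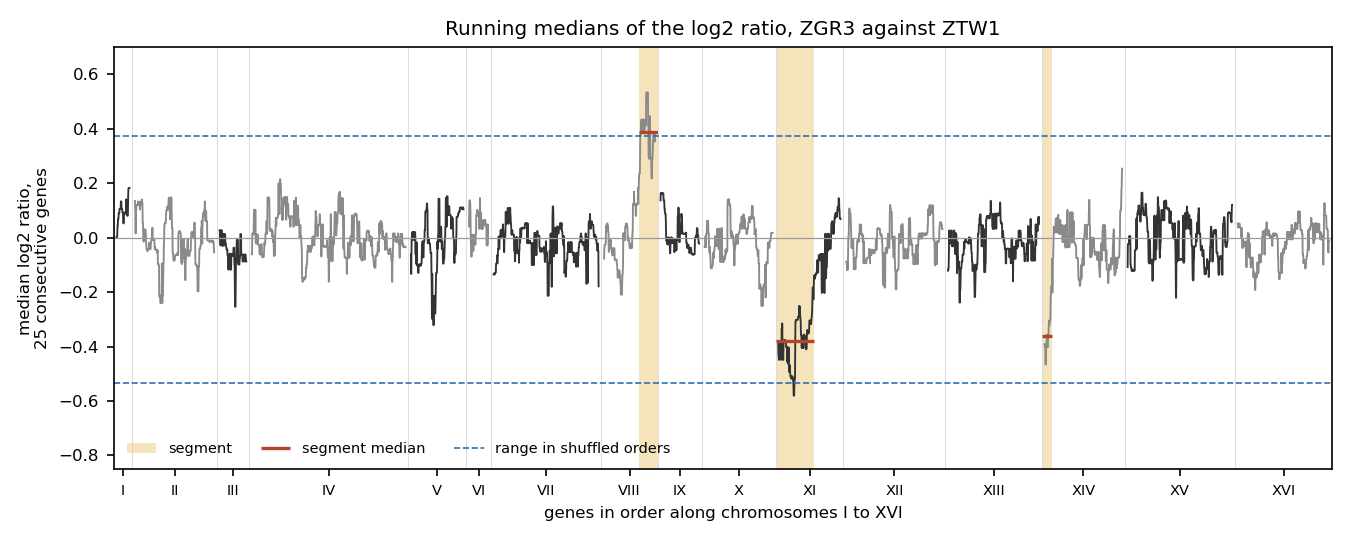
Median log2 ratio, ZGR3 over ZTW1, in windows of 25 consecutive genes along chromosomes I to XVI, with 1 library per strain; dashed lines mark the range in shuffled gene orders, shading the segments of chromosomes VIII, XI and XIV, and red lines their medians. The segments lie at 0.39, −0.38 and −0.36.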

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

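The tests in this part were chosen after the coverage values were seen. The share of a gene's length covered by reads was not used in the comparisons, and among 2586 genes with at least 200 reads in both libraries it differed by −0.198 points on average (SD 2.18 across genes). For 2 of these genes the loss in ZGR3 was over 20 points. CSM4, a meiotic chromosome gene, went from 87.7% to 60.3%, a loss of 27.4 points, with 240 reads in ZTW1 and 211 in ZGR3. SSB1 went from 68.1% to 41.8%, a loss of 26.3 points, with 1768 and 831 reads. The next largest loss among the 2586 genes was 13.2 points, for RPS16A, whose paralog RPS16B is named with the ribosomal proteins.

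For CSM4, fewer reads alone were checked against other genes. There were 44 other genes with at most 90% coverage in ZTW1 and reads at least as much lower in ZGR3. Their median loss was 1.46 points (SD 4.18 across genes) and the largest 11.1. The loss of CSM4 lay 6.199 SD beyond that median. CSM4 was picked for the largest loss of the 2586 genes, so a place beyond these 44 was given in advance. The comparison therefore cannot exclude fewer reads for CSM4. It shows only that such a drop in reads usually went with a small loss. For SSB1, fewer reads stay open too, since 0 of the 44 genes had reads as much lower. Another candidate explanation for SSB1 is that reads of part of the gene were assigned to its near-identical paralog SSB2. SSB2 had 4608 reads in ZTW1 and 5894 in ZGR3, and both genes together were 1.07-fold higher in ZGR3 (1.03 to 1.10) while SSB1 alone was 2.10-fold lower. A sequence difference between the strains in SSB1, such as copying from SSB2, may give this, as may a real difference in the expression of both genes; the reads were not analysed here, and no paralog was tested for CSM4.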

How the results depend on the processing

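The settings named here as added were chosen after seeing the data; the others were planned. The counts of 30 higher and 106 lower genes were 16 and 51 with a pseudocount of 5 RPKM, 14 and 61 at a mean RPKM of at least 10, and 9 and 32 with a 3-fold rule, each stricter by construction. With the pseudocount of 5 RPKM, which shrinks low genes by construction, chromosome XI had a median of −0.20 and the segments of VIII and XI medians of 0.33 and −0.32. In the added setting without the segments' genes, chromosomes VIII and XI turned to −0.028 and 0.015, because the genes that set their medians were left out. In the other settings both counts of genes stayed within 1.5 times of the main ones, and the numbers of lists standing apart did so in every setting. Of the 16 lists, 12 stood apart in each of 13 settings, none turned direction, and 7 further lists stood apart in at least 1; the cause was not tested. Of the named genes' values, 780 stayed within their counting intervals and 30 moved; of list medians, 481 and 22, and of chromosome medians, 150 and 8, with those of VIII and XI above turned. Leaving out 30 kb at chromosome ends was not run because the builds differ, and the added setting without the 15 outermost genes took its place, leaving too few genes for the segment of XV. No paired analysis was possible because each strain has 1 library, and for the same reason no replicate could be left out. Depth limits the lowest genes most: 5390 genes had at least 10 reads in ZGR3 and 3797 at least 100.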

Other observations

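The gene lists in this part were written after some of their members' values were seen; the tests on the members not seen before were fixed before their results, and the tests on the segments and the mitochondrial lists after. Phospholipid genes listed as Ino2 and Ino4 targets, with their regulators, had a median of −0.38 over 17 genes, with 15 below 0. Regulation by Ino2 and Ino4 was not tested for any member. INO1 was at −1.88, the phosphatidylserine synthase gene CHO1 at −0.66, EPT1 at −0.73 and INO2 itself at −0.58, while the repressor gene OPI1, which lies outside the segment of chromosome VIII, was at 0.36. The 10 members not seen before had a median of −0.36, at percentile 0.37 of random lists matched on mean expression but not on length. Genes of cohesin, the replication fork and its checkpoint had a median of 0.49 over 35 genes with 32 above 0, among them POL1 at 0.71, TOP2 at 0.64 and MCM3 at 0.61. Their 26 members not seen before had a median of 0.34, at percentile 100 of random lists matched on length and expression.

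The segments of chromosomes VIII, XI and XIV may reflect a difference in copy number between the strains. Their medians correspond to ratios of 1.31, 0.77 and 0.78, ZGR3 over ZTW1. A trend with coding length or GC content is argued against, since after correction for both the smallest absolute segment median was 0.34. A few extreme or low-count genes are argued against too. Of the genes with at least 100 reads over both libraries together, at least 85.9% lay on the segment's side of 0. The segments were cut from these same ratios, so a majority on that side was given, though not its size among well-counted genes. The more and less expressed genes of each of these segments had medians at most 0.071 apart. A shared dosage would give this, but so would any other regional shift unrelated to expression level. FBA1 and CWP2, the most abundant genes of the segment of XI, went the other way, both at 0.16. For the 29 genes from RPT1 to RAD27, inside that segment, the medians of the more and less expressed genes were further apart, at −0.60 and −0.41. The 10 leftmost genes of XV were left out of this test, and theirs were −0.76 and −1.21. DNA was not analysed here and the labels give no ploidy, so the sizes of the shifts cannot be matched to a copy number.

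Mitochondrial ribosomal protein and respiratory chain genes were lower in ZGR3, and a trend with coding length is argued against as the whole cause. After correction for length the median closest to 0 was −0.20, and both lists stayed at percentile 0 of random lists matched on length and expression. Location on the segments is argued against too, since the respiratory list has 0 genes there and the mitochondrial ribosomal list a median of −0.39 without its 8. A lower level of nuclear transcripts for mitochondrial proteins as a whole stays open: the tricarboxylic acid cycle was at percentile 37.9 of such lists, but its 18 members went both ways (SD 0.40 across genes). A difference between the strains, or in how far the cultures had entered stationary phase, was not tested and may also apply.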
